A study of Streptomyces iranensis with 8 samples.

How the data were processed

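The series holds 8 RNA-seq libraries of Streptomyces iranensis HM35, 4 of the wildtype and 4 of ΔbldA, grown for 48 h in TSB at 28 °C. Per the labels' protocols, total RNA was isolated with a column kit after bead beating, and libraries were made with a directional kit that marks strand. Whether counting used strand, the aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Each library has its own table of 9340 features with a name, start, end, length and strand. The sample titles carry a letter and a number (a-1, a-2, b-1, b-2) whose meaning is not given in the sources used here.

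The authors' raw read counts, so named in the file headers, were taken as estimated counts. In each library 37.0% to 40.4% of features had a count that was not whole, as when reads that fit several places are split. What the fractions stand for was inferred from the values. These deposited counts were rounded to whole numbers before testing. The authors also deposited RPKM, FPKM and TPM values and a transcript count, per the file headers; deposited RPKM matched the counts divided by length and library total, with a largest difference of 0.052% for features at 10 RPKM or more, and none of these normalised columns entered a test. The authors' transcript count is the read count times a mean read length per library over gene length, as worked out from the values, and was not used here. Feature lengths were multiples of 3 for 99.3% of features, so lengths are coding lengths.

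Totals were 25.2, 30.2, 30.5 and 26.3 M reads for wildtype a-1, a-2, b-1 and b-2, and 30.7, 40.7, 34.3 and 32.8 M for the ΔbldA libraries in that order. At this depth 12 to 73 features per library had a count of 0. TMM factors were 0.783 to 0.987 in wildtype and 1.02 to 1.27 in ΔbldA. CPM values are counts per 1000000 of the TMM-scaled library size, given as mean ± SD over 4 libraries.

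Genotypes were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr with its minimum count of 10 and minimum total of 15, TMM scaling, glmQLFit and glmQLFTest, no covariate), and p-values were adjusted by the Benjamini-Hochberg method. Features with an adjusted p under 0.05 are called changed, and the 2-fold rule adds an absolute log2 fold change of at least 1. Standard errors were computed as the absolute log2 fold change divided by the square root of the F statistic. The common dispersion was 0.0795. Gene lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 and with an estimated one. DESeq2 1.42.0 served as an alternative. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

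Before the data were examined, the tests, the alternatives, 27 gene lists and the rule for named genes were fixed. The lists were matched on symbols, as the tables hold no products: 19 had no member and 5 had at least 5 tested members. They covered polyketide synthases and peptide synthetases, ribosomal peptides, terpenes, cytochromes P450, aerial hyphae and sporulation, gas vesicles, ribosomal proteins, tRNA synthetases, respiration, glycolysis, acyl-CoA supply, arginine and ornithine, polysaccharide degradation, proteases, iron, nitrogen, phosphate, sigma factors, regulators, transporters, chaperones, oxidative stress, compatible solutes, cell division and transposases. Lists without members gave no result, and 13 more lists were written from the symbols before the first fit. A test of genes with a TTA codon and a test per biosynthetic region had been planned and were not run, because they need gene sequences and products that were not used here.

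Named genes are the 12 largest increases and 12 largest decreases among genes with a symbol, an adjusted p under 0.05, a mean count of at least 50 and no overlap of library ranges (88 genes higher and 58 lower qualified), up to 4 members of each list (lowest p in each direction, largest change, most abundant), whiA and the arginine genes. The rule had been written for genes with an annotated product, and a symbol took that place once the tables were seen to hold no products. The genes tuf at 5420759, lon, pstA, murG, paaI, paaJ, ssrA and rnpB were chosen after their values were seen. Locus tags without a symbol were limited to the largest changes in each direction. Symbols shared by several features (148 of 424) are told apart by start position, and reads shared by copies may have been split in the tables.

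Runs along a sequence, the 6000 nt limit and the counts at 8-fold and 64-fold were defined after the data were seen. For each feature of at least 2000 nt, the median of the nearest 5 tested features under 3000 nt on each side served as its neighbourhood, called or not, with bootstrap intervals that treat features as independent. Neighbours in a run are neighbours among tested features, so a stretch without listed features does not break a run. The described runs are lower runs with at least 20 members or a median log2 fold change of -5 or less and higher runs with at least 12 members.

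The scripts were tested on simulated counts for 9019 features of this comparison with 200 changed: 42% of 2-fold changes and 94% of 4-fold changes were recovered, 1 of the calls was false (0.73%), a planted list and a planted run were found, and 3 of 200 unchanged lists had p under 0.05. Far more features, 4199, changed in the data, so these shares check the scripts and need not hold for this comparison. Libraries of 1 genotype differed by a chi-square of 182 to 920 per feature, so by the rule set beforehand no pair was summed; this does not show that they came from separate cultures. Alternatives covered RLE, upper-quartile and library-total scaling, DESeq2 and limma-voom, low-count filters, leaving out RNA genes and transposase genes, a block for the title suffix or letter, libraries sharing a letter summed or correlated, a stricter threshold, glmTreat, and leaving out each library. Alternatives added after seeing the data left out both wildtype b libraries, combined library totals with leaving out RNA genes, and varied the run and length rules.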

Results

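RNA sequencing measured gene expression in Streptomyces iranensis HM35, a filamentous soil bacterium of a genus known for spore formation and for complex specialised metabolites, in 8 libraries of total RNA: 4 of the wildtype and 4 of a ΔbldA knockout, all after 48 h of growth in TSB medium at 28 °C. The bldA gene of Streptomyces encodes the leucine tRNA that reads the rare UUA codon, and its loss is known from other species of the genus to block aerial growth and the formation of many antibiotics. The comparison of both genotypes asked which transcripts changed when that tRNA was lost. Wildtype libraries held 25.2 to 30.5 M assigned reads and ΔbldA libraries 30.7 to 40.7 M. Of 9340 listed features, 424 carried a gene symbol and 8916 only a locus tag, and 9019 passed the low-count filter. Positions are those of the authors' tables, whose coordinates restart 4 times and so describe 5 sequences, the first with 9219 of the features and a last position of 11956507. The genome build is not given in the sources used here.

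The tables pair no feature with the name bldA, so the read count of the deleted gene was not analysed here. Among 76 features shorter than 100 nt, a length range that includes tRNA genes, 72 were tested, 7 rose and 4 fell in ΔbldA by edgeR's test. The strongest decrease among the 72 was a log2 fold change of -1.31 (adjusted p = 0.000221), from 11.9 to 4.79 counts per 1000000 reads (CPM). That feature kept at least 134 reads in each ΔbldA library, and among all 76 the lowest count in any ΔbldA library was 2. No listed feature of this length thus lost all its reads in ΔbldA. The knockout is taken from the labels and could not be checked with these counts. Each genotype's RNA was pooled from 3 replicates according to the series' design text, and nothing says that the 4 libraries of a genotype came from separate cultures, so p-values here measure only the spread between these libraries.

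In ΔbldA, the largest increases among genes with a symbol were those of thrS, a copy of rsgA, a copy of tuf and cydB. The feature with the symbol thrS, used for threonyl-tRNA synthetase, went from 1.71 ± 0.276 to 50.2 ± 16.5 CPM (SD, n = 4 per genotype), a 29.3-fold increase. It is 1221 nt long and its wildtype level was low. Whether a feature with only a locus tag codes for a further threonyl-tRNA synthetase could not be told without products, so the total for this enzyme is not known. The rsgA copy at 3395749, coding for a GTPase of ribosome assembly, rose 21.5-fold from 8.35 ± 2.78 to 179.5 ± 120 CPM. In ΔbldA this copy stood at 80.98 and 78.17 CPM in a-1 and a-2, and at 237.4 and 321.4 CPM in b-1 and b-2. The gene cydB, coding for a subunit of the high-affinity cytochrome bd oxidase, rose 10.1-fold from 110 ± 40.6 to 1111 ± 93.9 CPM. The crotonyl-CoA carboxylase/reductase gene ccrA at 1684501, whose product makes extender units for polyketides, was 79.6-fold lower, going from 100.2 ± 35.3 to 1.26 ± 0.155 CPM. Also lower were rfbC of dTDP-rhamnose synthesis, by 53.9-fold from 9.04 ± 4.43 CPM to a level near the floor, 0.16 ± 0.0406 CPM, and an asparagine synthase gene, asnB at 9711683, by 28.6-fold.

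The 12 largest increases among genes with a symbol spanned log2 fold changes of 4.87 ± 0.29 (SE) for thrS down to 1.84 ± 0.20 for the sodium/proton antiporter gene nhaA, and edgeR's adjusted p-values of the 12 ran from 5.37e-07 for hflX to 0.012 for gap at 11469445. The ribosome-associated GTPase gene hflX rose 6.66-fold to 1466 ± 185 CPM, and soxR, coding for a redox-sensing regulator, rose 6.65-fold. The tuf copy at 2094778, coding for an elongation factor Tu, rose 16.6-fold from 4.60 ± 1.24 to 76.4 ± 45.5 CPM. The other tuf copy, at 5420759, was far more abundant at 6571 ± 1590 CPM in wildtype and 6781 ± 1420 CPM in ΔbldA, with a log2 fold change of 0.05 ± 0.25. Reads shared between places may have been split in the tables, and how many the tuf copies share was not analysed here. Increases of 5.42-fold for hppD at 7264673 (4-hydroxyphenylpyruvate dioxygenase), 5.17-fold for cysC (adenylylsulfate kinase), 4.57-fold for gap at 11469445 (glyceraldehyde-3-phosphate dehydrogenase), 4.47-fold for aspA at 10559549 (aspartate ammonia-lyase) and 3.71-fold for pstS (phosphate-binding protein) completed the group. The rise of gap at 11469445 was not past the threshold in 3 alternative analyses. Its edgeR adjusted p was 0.0687 without both wildtype b libraries (range over alternatives 7.89e-05 to 0.0687). Another gap copy, at 8882875, was far more abundant, at 1546 ± 294 CPM in wildtype and 1806 ± 260 CPM in ΔbldA. Its log2 fold change was 0.22 ± 0.19 (edgeR, adjusted p = 0.356).

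Among genes with a symbol, a mean of at least 50 counts and library ranges that did not overlap, the 12 largest decreases included both ccrA copies that fell, 3 asnB copies and several catabolic genes. The ccrA copy at 6984, near the start of the first sequence, had a log2 fold change of -5.53 ± 0.65 (edgeR, adjusted p = 0.00012), from 121 ± 108 to 2.61 ± 0.735 CPM, and of -4.72 without wildtype b-1, the highest library. A further asnB copy at 503671 had a log2 fold change of -2.90 and, without wildtype b-1, of -1.91, and the copy at 860967 was 3.50-fold lower. The glucarate dehydratase gene gudD was 15.9-fold lower, the glycerol kinase gene glpK at 10428314 was 5.75-fold lower, and the trehalose synthase gene treS was 3.95-fold lower. The methylmalonyl-CoA mutase gene mutA went from 325.5 ± 57.1 to 84.96 ± 15.0 CPM (3.83-fold; edgeR, adjusted p = 2.39e-05). Decreases of paaN and paaF rested mainly on 1 library: paaN stood at 1830 CPM in wildtype b-1 and at 26.6 to 51.45 CPM in the other wildtype libraries, against 17.8 ± 3.95 CPM in ΔbldA. Without wildtype b-1 the log2 fold change of paaN was -1.01 instead of -4.77, and that of paaF was -0.51 instead of -3.22. Both calls were kept without wildtype b-1. They were lost without any 1 of the ΔbldA libraries, where the log2 fold changes stayed at -4.88 to -4.63 for paaN (edgeR, adjusted p 0.0514 to 0.06) and -3.27 to -3.18 for paaF (adjusted p 0.074 to 0.0793).

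**Figure D1:**
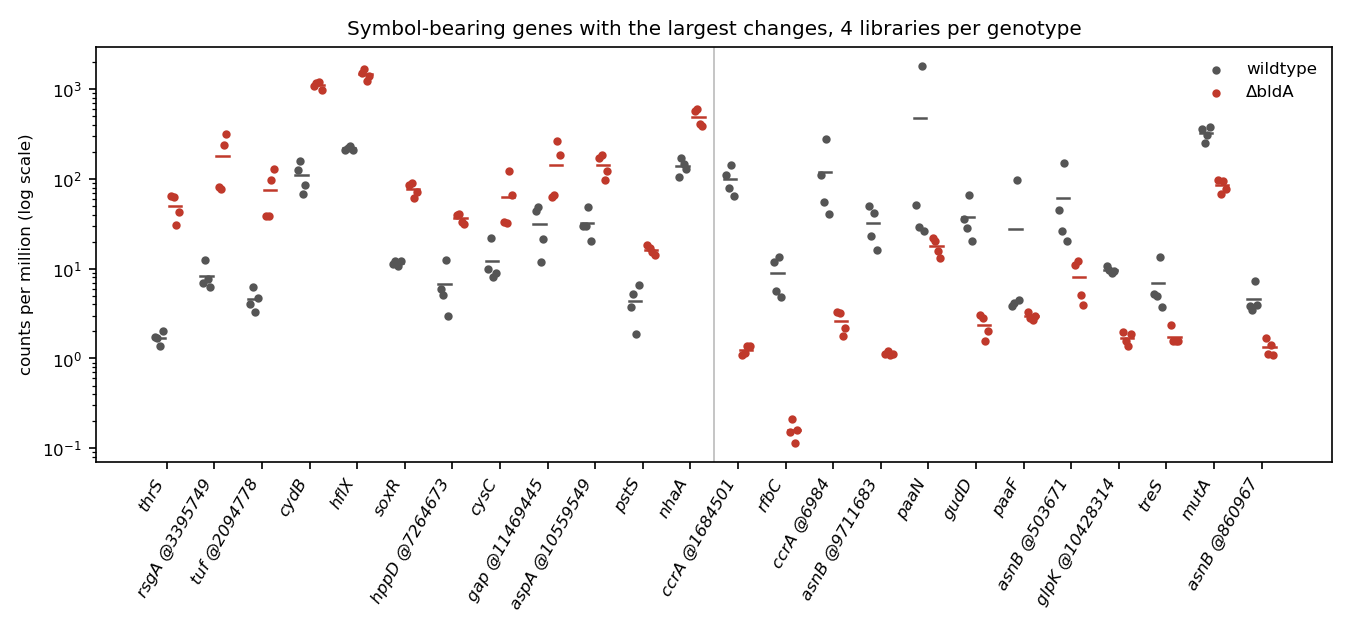
CPM on a log axis for the 12 genes with a symbol that rose most (left of the grey line) and 12 that fell (right), chosen as the largest changes among genes with library ranges that did not overlap, with 1 point per library, 4 wildtype libraries in grey and 4 ΔbldA libraries in red, and a bar at each mean; numbers after @ are start positions where a symbol occurs more than once. Larger decreases with overlapping ranges, such as those of paaI and paaJ, are not drawn, and paaN and paaF each have 1 wildtype point, b-1, far above the other 3.

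Across all features, 4199 of 9019 (46.6%) changed at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, 1957 higher and 2242 lower in ΔbldA. At least 2-fold changes numbered 2257, of which 837 were higher and 1420 lower, and at least 8-fold changes numbered 82 higher and 374 lower. Decreases of at least 64-fold were seen for 75 features and increases of that size for 0. The library ranges of both genotypes did not overlap for 4042 of the 9019 tested features (44.8%), called or not. With 8 independent libraries, chance alone would give 2.86%. Libraries of a genotype may share pooled RNA or a culture, so that share may not be the right baseline here. Scaled on library totals alone, the split was 2887 higher and 1440 lower (33.3% lower, against 53.4% with TMM), because the median of all features then lay at a log2 fold change of 0.30 instead of -0.03; changes are therefore given relative to that median. Of 417 tested genes with a symbol, 93 rose and 75 fell.

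The strongest changes belonged to features with a locus tag only. SIRAN_RS36445 (9114063 to 9114506, reverse strand) went from 9765 ± 3430 to 10.2 ± 0.84 CPM, a 957-fold decrease. SIRAN_RS43440 (10864823 to 10865602, forward strand) was 533-fold lower, from 62.3 ± 20.9 to 0.109 ± 0.0775 CPM. Its ΔbldA level lay near 0, so the size of that fold is imprecise. The neighbours SIRAN_RS27385 and SIRAN_RS27390, which start at 6902456 and 6902770 on the forward strand, rose 51.1-fold and 44.6-fold. The tables give no product for these features.

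In the gene lists, calls came to 3 of 4 tested phosphate uptake genes and 5 of 8 acyl-CoA supply genes, and to 0 of 10 ribosomal protein genes, against 46.6% of all features. The acyl-CoA supply and nitrogen assimilation lists used here were written later from the symbols, as the planned lists of those names had no member. Of 27 gene lists fixed before the data were examined, 8 had members by symbol, since the tables give no products, and 13 more lists were written from the symbols before gene values were examined. All of them are small samples of their pathways, and the settings named for a list below are those with larger shifts in its counts, not every setting with a shift. In the phosphate list, pstS, pstC and pstA of the high-affinity phosphate transporter rose out of 4 tested members, with log2 fold changes of 1.89 ± 0.32, 1.78 ± 0.29 and 1.49 ± 0.24, and phoU stood at 0.14 ± 0.10 (edgeR, adjusted p = 0.271; on library totals 0.47, adjusted p = 0.0288, range over all settings 0.0288 to 0.444). Their levels were low, 4.36 ± 2.00 CPM for pstS in wildtype and 16.2 ± 1.77 CPM in ΔbldA. The genes pstS (5687127 to 5688248) and pstC (5688364 to 5689353) lie close together on the forward strand, so their calls need not be independent. Among 8 respiratory chain and ATP synthase members, cydB rose and atpB of the ATP synthase fell from 1174 ± 161 to 722.6 ± 140 CPM, while the more abundant atpD had a log2 fold change of -0.50 ± 0.22 (edgeR, adjusted p = 0.0969). The decrease of atpB was not past the threshold when scaled on library totals (log2 fold change -0.37, adjusted p = 0.213; range over alternatives 0.00184 to 0.213) or with libraries sharing a letter summed (-0.63, adjusted p = 0.101).

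Of 8 tested arginine and ornithine metabolism genes, 0 passed the threshold in edgeR, 1 had an unadjusted p under 0.05, DESeq2 called 1 lower and limma-voom 1 higher. Without wildtype b-1, 2 were higher and 2 lower. The ornithine carbamoyltransferase gene argF went from 96.5 ± 73.7 to 44.5 ± 13.3 CPM (log2 fold change -1.12 ± 0.52; edgeR, adjusted p = 0.105), and the argininosuccinate lyase gene argH at 2776100 had a log2 fold change of -0.87 ± 0.34 (adjusted p = 0.0568). Without wildtype b-2, where it was highest at 198.9 CPM, the log2 fold change of argF was -0.48 (adjusted p = 0.363). Without wildtype b-1, where it was lowest, its adjusted p was 0.0104 (range over all settings 0.0104 to 0.363) and that of argH at 2776100 was 0.0112 (range 0.0112 to 0.212). The agmatinase-type gene speB at 10964327 had 5.63 ± 7.46 CPM in wildtype and 13.6 ± 5.51 CPM in ΔbldA (adjusted p = 0.193), and without wildtype b-1 its log2 fold change was 2.83 (adjusted p = 0.000245; range 0.000245 to 0.342). The ornithine aminotransferase gene rocD at 1557956 had a log2 fold change of 0.46 ± 0.64 and, without wildtype b-1, of 1.58 (adjusted p = 0.0112; range 0.00799 to 0.886). Ribosomal proteins had 0 calls among 10 members in edgeR, DESeq2 and limma-voom and 0 with an unadjusted p under 0.05 in edgeR. Without wildtype b-1, 1 of them was lower. The most abundant was rpsB at 2225 ± 679 and 1993 ± 302 CPM. Near the floor were rpsR at 10526647, rpmG at 10525020 and rpmB at 10524696, with 1.29, 0.488 and 1.06 CPM in wildtype. The sporulation regulator gene whiA, the single member of the aerial hyphae and sporulation list, had 105.5 ± 19.1 and 101.1 ± 13.2 CPM (log2 fold change -0.06 ± 0.16; edgeR, adjusted p = 0.779).

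Chaperones and ATP-dependent proteases had 2 of 8 members higher, clpB at 5849809 (1.86-fold) and lon (1.46-fold), while the abundant chaperonin gene groL at 6699389 stood at 9902 ± 2680 and 11090 ± 789 CPM. On library totals 4 of the 8 were higher. Compatible solute genes had 1 of 7 members lower, treS, and ectB of ectoine synthesis had a log2 fold change of -0.46 ± 0.24 (edgeR, adjusted p = 0.144). Without wildtype a-2, 4 of the 7 were lower, with ectB at -0.66 (adjusted p = 0.0101; range over all settings 0.0101 to 0.712), and DESeq2 called 3 lower, while on library totals 2 were higher and 1 lower. Of 4 cell division and peptidoglycan genes, murA and murG fell, murA from 395.5 ± 106 to 194 ± 15.8 CPM, and murA alone was called without wildtype a-1, ΔbldA b-1 or ΔbldA b-2, with upper quartiles, with the suffix block, with libraries sharing a letter summed, and on library totals with or without RNA genes. Adjusted over the list alone, all 8 of these planned lists gave the same counts as over all genes.

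Translation factors and aminoacyl-tRNA synthetases had 5 of 18 members higher and 1 lower, raiA, whose decrease from 372.4 ± 172 to 198.4 ± 27.6 CPM was marginal (edgeR, adjusted p = 0.0351). It was not past the threshold without wildtype a-1 or b-1 or ΔbldA a-1, a-2 or b-2, with limma-voom with or without a correlation within letters, with the suffix block or on library totals with or without RNA genes (adjusted p over all settings 0.00857 to 0.109). The most abundant member, fusA, had 6916 ± 2200 and 7396 ± 1990 CPM. In acyl-CoA precursor supply, 5 of 8 members fell, among them both of the ccrA copies named above and mutA, and 0 rose. Scaled on library totals, 4 of those 8 were lower and 1 higher. Among 39 amino acid biosynthesis genes 13 rose and 7 fell, with proC of proline synthesis 2.74-fold higher and 4 of the 7 decreases being asnB copies. Over the alternatives 9 to 18 members of that list were higher, 18 of them on library totals, and 7 to 9 were lower. Redox defence genes had 5 of 19 higher and 5 lower, against 8 and 5 on library totals, 5 and 2 with limma-voom, 5 and 3 without ΔbldA a-1, and 4 and 3 without ΔbldA a-2 or b-2. The thioredoxin gene trxA at 8128089 was 2.16-fold higher, and the catalase genes katE and katG were 2.74-fold and 2.61-fold lower, katG from 1132 ± 106 to 433.3 ± 123 CPM. The ergothioneine gene egtC had a log2 fold change of -2.09 ± 0.59 with wildtype and ΔbldA libraries overlapping, and of -1.42 without wildtype b-1. It was not past the threshold with limma-voom (-1.65, adjusted p = 0.0514) or with a correlation within letters (adjusted p = 0.0608; range over alternatives 0.000364 to 0.0608).

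Among 28 sugar and polyol genes 3 rose, with deoC 2.93-fold higher, and 9 fell, with gudD and glpK at 10428314 lowest; on library totals 6 were higher and 7 lower. Another glpK copy, at 9322831, had 192.1 ± 286 and 240.6 ± 143 CPM (log2 fold change 0.32 ± 0.89; edgeR, adjusted p = 0.789), and without wildtype b-2, where it stood at 620.7 CPM, its log2 fold change was 2.29 (adjusted p = 0.00418; range over all settings 0.00418 to 0.992). Central carbon genes had 4 of 28 members higher, with gnd at 6097171 of the pentose phosphate pathway 2.40-fold higher, and 2 lower, with the fumarase gene fumC at 11315562 3.13-fold lower; without wildtype b-1 there were 8 higher and 4 lower, with the suffix block 2 and 2, and on library totals 6 and 1. DNA replication and repair had 4 of 13 higher and 1 lower: gyrB of DNA gyrase went from 597.3 ± 60.7 to 1282 ± 176 CPM, nth was 2.42-fold higher and recQ was 2.64-fold lower. On library totals 8 of the 13 were higher, and without wildtype b-1 2 were lower.

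Aromatic compound catabolism had 1 of 13 higher, hppD at 7264673, and 5 lower, of which paaN, paaF, paaI and paaJ of phenylacetate use were far higher in wildtype b-1 than in the other wildtype libraries. The 5 decreases came to 0 with limma-voom, with the suffix block and without ΔbldA a-1, b-1 or b-2, to 1 with DESeq2, with libraries sharing a letter summed, with the letter as a block and without ΔbldA a-2, and to 3 without wildtype b-1. Type VII secretion had 2 of 7 lower, with eccD at 4700889 2.11-fold lower, and 1 lower without wildtype a-2 or ΔbldA b-2 or on library totals, while isoprenoid and hopanoid synthesis had 1 of 9 higher, hpnC, and 3 lower, with uppS at 1995518 3.14-fold lower. The call of hpnC was kept only without wildtype b-1 or ΔbldA b-2 among the settings without 1 library, and 1 to 4 members of that list were lower in those settings, against 2 higher and 1 lower on library totals. Cobalamin synthesis had 2 of 6 higher, with cbiQ 1.93-fold higher, and 1 lower, cbiE, which was not past the threshold on library totals.

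Nitrogen assimilation had 1 of 6 higher, the glutamine synthetase gene glnA at 8547424, a call lost with the suffix block (adjusted p = 0.0514) and with libraries sharing a letter summed (adjusted p = 0.0661; range over all settings 0.001 to 0.0661). The more abundant glnA at 8613034 went from 1010 ± 525 to 550.7 ± 78.5 CPM (edgeR, adjusted p = 0.0723). It was lower without wildtype b-1 (log2 fold change -1.14, edgeR adjusted p = 0.0034, range over all settings 0.0034 to 0.222), where that list had 2 higher and 1 lower. This copy was also lower with DESeq2 (adjusted p = 0.0403) and, in edgeR, with libraries sharing a letter summed (adjusted p = 0.0196) and without both wildtype b libraries (adjusted p = 0.0106). Purine and ureide degradation had 0 of 6 past the threshold in edgeR, DESeq2 and limma-voom, with 1 at an unadjusted p under 0.05. Its member pucD had a log2 fold change of 1.19 (edgeR, adjusted p = 0.208) and, without wildtype b-1, of 2.45 (adjusted p = 0.0024; range 0.0024 to 0.381), and 1 member was lower without wildtype a-2.

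As sets, none of the 18 lists with at least 5 tested members passed the camera test after Benjamini-Hochberg adjustment. The smallest adjusted p was 0.332, shared by acyl-CoA precursor supply (lower) and translation factors (higher). With an estimated correlation, their adjusted p-values were 0.92 and 0.954.

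Many of the decreases lay side by side on the genome. Runs were defined, after the data were seen, as at least 8 features changed at least 2-fold in the same direction with at most 2 tested features between neighbours. There were 35 runs of lower features, with 484 members, and 8 runs of higher features, with 83 members. Over 1000 shuffles of the order of the first sequence, at most 5 lower runs and 1 higher run appeared, against 33 and 8 in the real order (permutation p = 0.001 for each, the smallest that 1000 shuffles can give).

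The run with the most members held 35 lower features between 9572346 and 9693973 on the first sequence, 122 kb, with a median log2 fold change of -6.45. Its summed level went from 37280 ± 4970 to 522.6 ± 272 CPM, and its longest feature had a coding length of 30648 nt. The longest stretch without a listed feature within that run was 20 kb. A second run followed from 9704648 to 9732154, with 21 lower features including asnB at 9711683 and rfbC and a median of -5.94. Between 1090891 and 1204592, 12 lower features, 4 of them of at least 6000 nt, had a median of -6.98 and a summed level that went from 9226 ± 4560 to 76.6 ± 15.6 CPM, and a stretch of 56 kb within that span held no listed feature. The run from 487 to 94690, with ccrA at 6984 and 17 members, had a median of -5.59. The run from 772480 to 796588, with 19 members, had a median of -5.53. Their longest stretches without a listed feature were 11.9 kb in the run from 487 and 0.423 kb in the run from 772480.

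**Figure D2:**
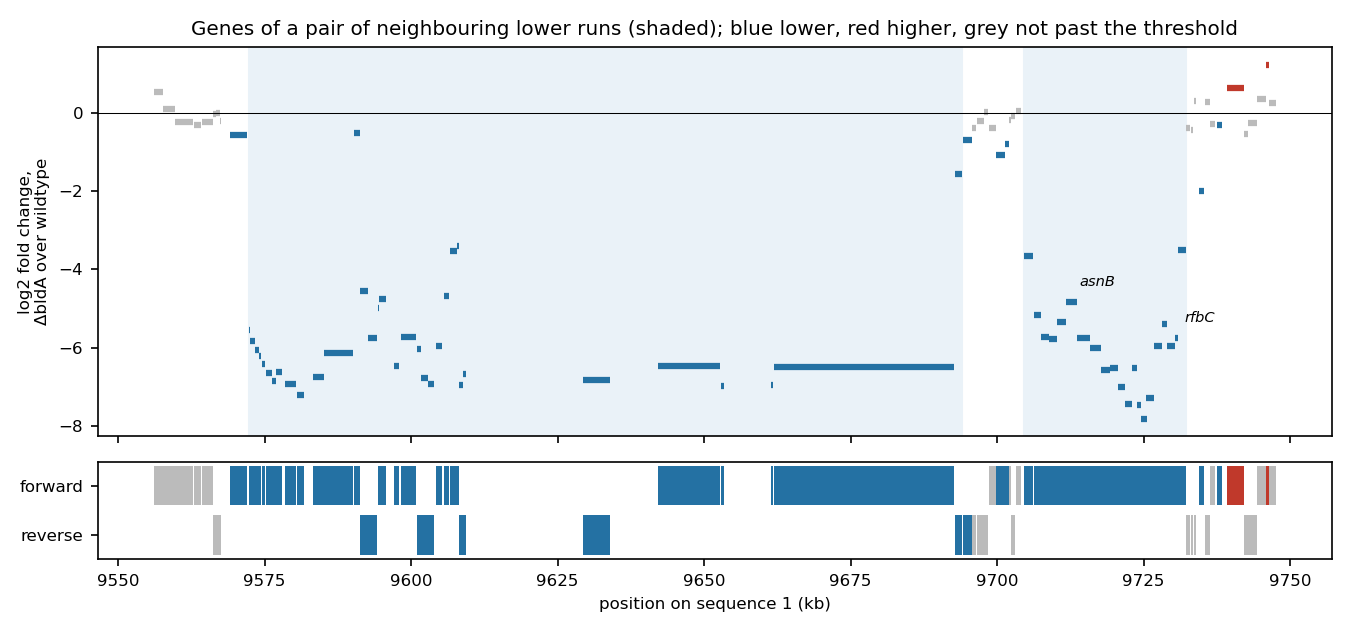
Log2 fold change of ΔbldA over wildtype for the 89 tested features from 9557346 to 9747154 on the first sequence (upper panel, each bar spanning the feature) and their strands (lower panel), with the longest lower run and its neighbour shaded; 63 features were lower (blue), 2 higher (red) and 24 not past the threshold (grey). The shaded runs are 10.7 kb apart.

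Further long runs of lower features lay between 7340226 and 7369482 (30 members, median -3.48), 11034382 and 11155515 (32 members, median -4.27), 10585606 and 10621824 (22 members, median -2.03) and 869217 and 970574 (20 members, median -2.70, with a longest feature of 20832 nt). The run from 1903909 to 1919242 had 12 members and a median of -6.03, but its summed wildtype level varied 83.4-fold between libraries, from 41.85 CPM in b-2 to 3490 CPM in b-1, against 13.6 ± 1.39 CPM in ΔbldA. A run of 9 features between 36201 and 46984 of the second sequence had a median of -5.14. Stretches without a listed feature reached 21.9 kb in the run from 869217, 19 kb in that from 11034382 and 6.77 kb in that from 10585606.

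Higher runs were fewer. The run from 7558686 to 7683586 had 14 members, 4 of them of at least 6000 nt with a longest of 25704 nt, and its summed level rose from 191.4 ± 10.2 to 816 ± 82.2 CPM. The run from 3395296 to 3435189, with 13 members including rsgA at 3395749 and cysC, had a median of 2.88 and levels of 143.4 ± 75.6 and 912.9 ± 536 CPM. In ΔbldA the run from 3395296 stood at 477.9 and 499.4 CPM in a-1 and a-2, and at 1604 and 1070 CPM in b-1 and b-2. The run from 10533399 to 10545277 had 12 members and a median of 2.17. Stretches without a listed feature reached 33.3 kb in the run from 7558686, 22.3 kb in that from 3395296 and 0.436 kb in that from 10533399.

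**Figure D3:**
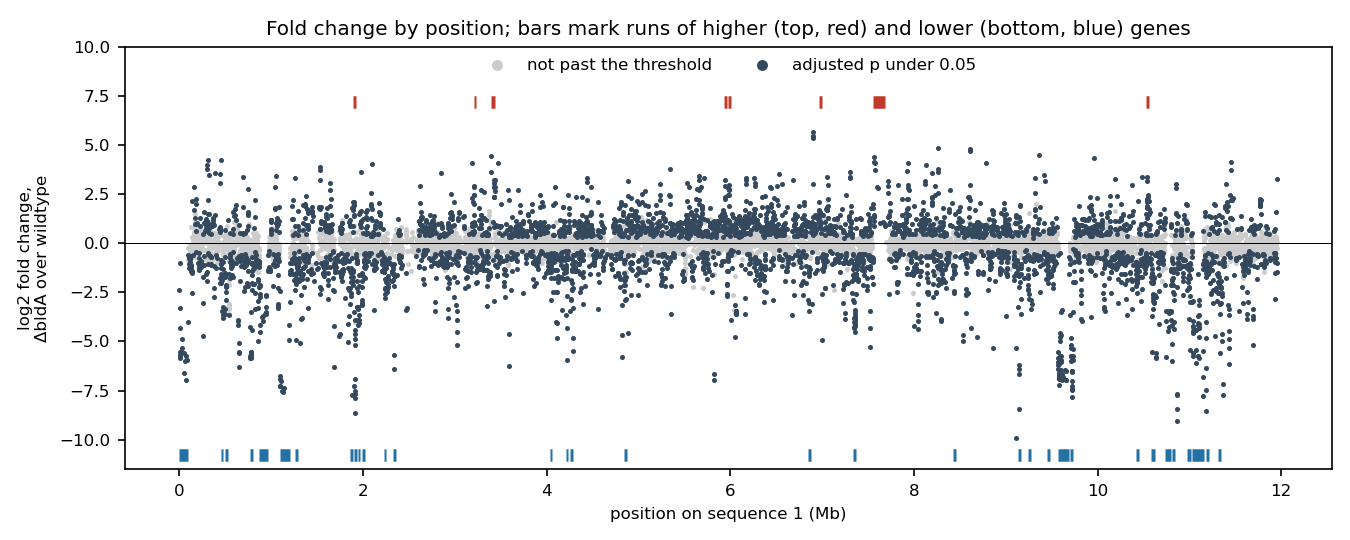
Log2 fold change of ΔbldA over wildtype for each tested feature (points, dark where the adjusted p was under 0.05) against its start on the first sequence in Mb, with bars marking the 8 runs of higher features (top) and the 33 runs of lower features (bottom). Lower runs gather in the outer parts of the sequence, with some in the middle, and the largest decrease, -9.90, lies near 9.11 Mb.

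By position, the share of features at least 2-fold lower was 25% in the first Mb and 27.7% in the second Mb of the first sequence, 19.4% to 21% from 9 Mb to the end, and 6.32% between 5 and 6 Mb. The share at least 2-fold higher was highest between 6 and 7 Mb, at 14.1%. Long genes fell more often than others: of 54 features of at least 6000 nt, a limit chosen after the data were seen, 31 (57.4%) were lower and 6 higher, against 24.9% lower among all tested features. From 6000 to 9000 nt 17 of 22 were lower (77.3%), and from 9000 nt 14 of 32 (43.8%). The 54 had a median log2 fold change of -0.67 (camera, p = 4.27e-06; p = 0.0352 with an estimated correlation of 0.0647). Polyketide synthase and peptide synthetase genes are typically long, but the tables give no products by which to assign them.

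The libraries separated first by genotype. The first principal component held 75.5% of the variance and divided wildtype from ΔbldA, and Spearman correlations across features were 0.976 to 0.994 within ΔbldA, 0.940 to 0.987 within wildtype and 0.838 to 0.893 between genotypes. Correlations across features treat genes as units, which are not independent replicates. The second component (10.8%) parted wildtype b-1 from wildtype b-2, the least alike wildtype libraries. Without both wildtype b libraries, 3697 features changed, 1675 higher and 2022 lower. RNA-length features, defined as 5S rRNA, rnpB, ssrA, ffs, features shorter than 100 nt and features whose length is no multiple of 3, took 22.13% to 38.67% of reads in wildtype and 12.19% to 33.91% in ΔbldA.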

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

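The tests on splits, scaling, runs and long features were chosen after the results were seen; the limits of both long-feature tests were set before the values of those tests were computed.

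Of 184 groups of 4 libraries searched, 10 had a library far from the other 3 on the log2 scale (gap to the nearest library over the whole range), and chance gives about 1 in 20. Ratios of gap to range follow each value. In ΔbldA, treS was highest in a-1 at 2.35 CPM against 1.55 to 1.56 (0.989), whiA was lowest in a-2 at 81.7 CPM against 105.6 to 111 (0.838), and eccE was highest in a-2 at 153.2 CPM against 138.5 to 140.8 (0.832). Wildtype b-1 was highest for paaF at 97.2 CPM against 3.85 to 4.54 (0.949), speB at 10964327 at 16.8 against 1.62 to 2.31 (0.853), paaN at 1830 against 26.6 to 51.45 (0.844) and asnB at 860967 at 7.27 against 3.49 to 3.93 (0.84). Wildtype b-2 was highest for glpK at 9322831 at 620.7 CPM against 41.69 to 60.84 (0.86) and lowest for eccE at 138.3 against 159.9 to 164 (0.85), and wildtype a-1 was lowest for rocD at 6870741 at 2.329 against 2.879 to 3.003 (0.833).

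Genotype gave 4199 changed features, and the other 34 of 35 splits of the 8 libraries into 4 and 4 gave at most 0, so 1 of 35 splits, the genotype itself, reached that count. The same held for the 2257 features changed at least 2-fold, where 1 of 35 splits reached the count and the highest other was 0. Each of the other 34 splits put both genotypes in both groups, so a large genotype difference counted as spread within groups. The counts of 0 therefore do not show how many calls a split of libraries of like genotype would give.

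More features fell than rose in ΔbldA. For at least 2-fold changes the share of decreases was 62.9% with TMM, 61.1% with RLE, 58.9% with upper quartiles and 60.8% with DESeq2, but 41% on library totals alone and 49.6% on library totals without RNA genes. Library totals shift the median of all features to 0.30, so the excess at that size depends on where the middle of the features is set, and scaling may account for it. For at least 8-fold changes, 72.4% were lower on library totals alone (322 lower and 123 higher), so that choice of scaling did not account for the excess at this size. The genotype stays open as an untested cause of that excess, since RNA was pooled within each genotype per the series' design text and separate cultures are not stated.

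Runs of lower neighbours could have come from chance order of genes or from a single library. Shuffled orders argue against a random order of the changed features (permutation p = 0.001, the smallest that 1000 shuffles can give). They treat neighbours as independent, so they do not bear on any single run or on why neighbours changed together. Without wildtype b-1, 93.8% of the members of lower runs were still at least 2-fold lower. Co-transcription and shared regulation in ΔbldA remain candidate explanations that these tables do not test.

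Long features fell more often, and 2 explanations were tested against shorter neighbours, called or not; a first comparison of features outside runs (medians of -0.22 from 3000 to 6000 nt and -0.46 above) was set aside, because runs consist of changed features. Length as such predicts that features of 3000 to 6000 nt lie below their neighbours: the median difference in log2 fold change was -0.283 (bootstrap 95% interval -0.412 to -0.165, 163 features), but -0.0257 (-0.125 to 0.059, 440 features) from 2000 to 3000 nt. It was -0.26 (-1.72 to 0.186, 22 features) from 6000 to 9000 nt and -0.246 (-0.509 to 0.116, 32 features) at 9000 nt and above. Length may contribute from 3000 to 6000 nt, and the wide intervals above that leave open how the difference goes on. Lower stretches of the genome predict that features of at least 6000 nt lie level with their neighbours: the neighbours had a median of -0.71, and the median difference was -0.26 (-0.51 to 0.07, 54 features), which includes both 0 and the limit of -0.2. For features of at least 6000 nt, lower stretches and a decrease of their own cannot be told apart, because 54 features leave that interval wide. The share called lower did not keep growing with length, being 77.3% from 6000 to 9000 nt and 43.8% above.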

How the results depend on the processing

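The alternative settings were written before the files were seen, except that the setting without both wildtype b libraries, library totals without RNA genes, the run and length rules and the 8-fold counts were added after seeing the data. Counts of changed features ran from 3194 (libraries sharing a letter summed) to 4454 (DESeq2), and 0 features called in both turned direction in any alternative. Leaving out 1 library gave 3582 to 4230 changed features. On library totals alone 1440 features were lower, 1496 were at least 2-fold higher and 252 were in higher runs, since the median of all features moved to 0.30; with RNA genes also left out, 161 were in higher runs; the cause of the scaling difference was not tested. At an adjusted p under 0.01, 1285 were higher. A glmTreat test against 2-fold called 1177, 356 higher and 821 lower. With no feature between members, 298 features were in lower and 49 in higher runs, and at a limit of 9000 nt 14 of 32 long features were lower (43.8%, against 57.4% at 6000 nt); the cause was not tested. The replicate block on the title suffix gave 3615 changed features. Libraries with the same suffix deviated from their group means with correlations of -0.153 to -0.0209, so no shared deviation by suffix was seen. Those correlations cannot tell whether libraries with the same suffix were handled together. The cause of the lower count was not tested. Over 70 named genes, 47 of them called, 30 of 964 comparisons with alternatives lost a call (9 genes) and 19 gained it. Without 1 library, 23 of 552 lost it (paaN, paaF, raiA, hpnC and dxs at 127974 of the second sequence) and 9 gained it. None reversed. The gene hpnC had adjusted p 0.0521 to 0.0790 where it lost the call. No list passed the adjusted camera test in any alternative. The TTA-codon and biosynthetic region tests could not be run in any setting, and pseudocount alternatives did not apply to counts. In simulated counts with this number of libraries and 200 changed features, 42% of 2-fold changes were recovered. Since 4199 features changed in the data, that share need not hold here, and depth was not varied.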

Other observations

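The tests on abundant RNAs, length classes and library pairs were chosen after the results were seen. The tmRNA gene ssrA, whose RNA frees stalled ribosomes, was among the most abundant features and fell from 50290 ± 7680 to 18090 ± 462 CPM (log2 fold change -1.48 ± 0.27; edgeR, adjusted p = 0.0019, lower in 4 of 4 ΔbldA libraries). The RNase P RNA gene rnpB had 36450 ± 6000 and 47040 ± 21100 CPM (edgeR, adjusted p = 0.474).

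Outside runs, which leaves out many changed features, the median log2 fold change by coding length was as follows. It was 0.08 for 1572 features under 500 nt, 0.06 for 3372 features of 500 to 1000 nt, -0.05 for 2872 features of 1000 to 2000 nt, -0.10 for 405 features of 2000 to 3000 nt, -0.22 for 131 features of 3000 to 6000 nt and -0.46 for 34 longer ones. The share called lower outside runs went from 17.1% in the shortest class to 44.1% in the longest. Runs are picked by the change, so these classes do not test length. With runs included, the share was 77.3% from 6000 to 9000 nt and 43.8% above.

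In ΔbldA, libraries sharing a letter were more alike (Spearman 0.993 and 0.994 across features) than libraries of different letters (0.976 to 0.983). In wildtype, libraries sharing a letter were not (0.940 and 0.982, against 0.953 to 0.987 for different letters).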
